A study of Rattus norvegicus with 16 samples.

How the data were processed

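RNA of the myocardium of Sprague-Dawley rats at day 7 was measured in 16 libraries, 4 each of control, Cx43-wt, S282A and phosphatase inhibitor Lats-1, per the labels. Per the labels' protocols, RNA was checked on agarose gels, with a NanoPhotometer and with a Bioanalyzer, and libraries were made with the NEBNext Ultra RNA kit for Illumina. Per the submitters' processing notes, which give no roles or order, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 were used by the authors with the Rnor_6.0 build. The deposited values are FPKM made by the authors, that is reads of a gene per kilobase of its listed length and per 1e+06 of a library total, for 33957 genes of which 1074 have provisional identifiers. The FPKM of each library multiplied by gene length were whole multiples of 1 number within 0.01 for 100% of genes, which gave back the whole reads behind them, 14.2 to 18.0 M per library.

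Gene symbols and positions come from the deposited table; the reference gene table provided, of another assembly, shared 0 of its identifiers and was used for gene names only. Symbols missing from the deposited table were looked up under older names, which matched 16 of 664 matched list genes out of 687. The reads were not realigned, and isoforms, variants and an introduced transcript were not analysed here.

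FPKM were scaled per library by the median ratio to the geometric mean of all libraries. The deposited values already carried such a scaling, as the factors found were the same in all 16 libraries and lay 0.00554 from 1. Genes with a mean of at least 1 FPKM over the 16 libraries, 12935 in all, were tested on log2(FPKM + 1) with a linear model in limma 3.58.1 under R 4.3.3 (empirical Bayes with a trend in the prior variance). All 16 libraries stood in 1 fit with group as the only factor, because each group has 4 libraries of the same tissue. The 5 comparisons were S282A against Cx43-wt, S282A against control, Cx43-wt against control, the inhibitor group against control and the inhibitor group against S282A. The tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes of a comparison, and the threshold was an adjusted p of 0.05.

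In all, 41 lists of pathway genes and cell type markers were fixed before the data were examined, as were the comparisons, tests and the rule for naming genes. The 36 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Lists for B and plasma cells, Y-linked genes and Xist, mesothelium and epicardium, neutrophils, and skeletal muscle had too few tested members and were not tested. Members of each list were also adjusted over that list alone. Genes were named by a rule: the genes of the series title and labels; the 3 higher and 3 lower with the smallest unadjusted p where no gene passed; and list members with the smallest p. At most 4 members per list were allowed, and the text prints 1 or 2 of them for most lists, 96 genes in all. Symbols starting with LOC, AABR, RGD or AC were passed over, and so were RF, AY and NEWGENE identifiers, a skip added after the data were seen.

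Other settings fixed at the same time were deposited FPKM without scaling, quantile normalization, a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, only the 2 groups compared, library weights, the replicate number as a block and leaving out each library in turn. The numbers 6 and 7 occurred in S282A alone, so under the block S282A 6 and S282A 7 did not inform any difference. Added after seeing the data were scaling to total recovered reads, voom on recovered reads, removal of each library's trend on gene length (natural spline with 4 degrees of freedom), fits without the 4 libraries richest in short genes (lists also at an estimated correlation) or the 3 highest in atrial genes, both features as covariates, fry in place of camera and exact permutation of list means between the 2 groups. An exact permutation of 4 against 4 libraries can give a two-sided p of 0.0286 at the smallest. Correlations across libraries were tested with 100000 permutations, two-sided. Libraries apart from their group were found with Dixon's ratio of gap to range, in groups of 4. Each comparison was repeated over the 35 splits of its 8 libraries. The values of 1 single gene are not reported here.

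The procedure was tested on simulated data in 5 draws with 200 changed genes and the spread of these libraries. It called 33.3% to 47.8% of genes changed 1.5-fold, 68.8% to 79.1% of those changed 2-fold and 90.9% to 97.0% of those changed 4-fold, with 4 to 12 unchanged genes called. A list raised by 0.5 on the log2 scale was called in all 5 draws and 0 of the 35 others were. With no gene changed, 0 genes and 0 lists were called. The simulated genes varied independently, so these draws do not test camera where list members vary together. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.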

Results

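RNA from the myocardium of Sprague-Dawley rats was sequenced at day 7 in 16 libraries, 4 in each of 4 groups. The labels name a control, Cx43-wt (the normal form of connexin 43), S282A (connexin 43 with the serine of the named position replaced by alanine), and a phosphatase inhibitor Lats-1, here called the inhibitor group. They do not say what the control received, or whether the inhibitor was given alone or with S282A. The series' design text speaks of mouse hearts, while each sample is labelled as rat. Gene reads recovered from the deposited values numbered 15.3 to 16.4 M per library in control, 15.4 to 18.0 M in Cx43-wt, 15.1 to 17.4 M in S282A and 14.2 to 16.5 M in the inhibitor group. Mitochondrial genes took 27.7 ± 3.19% of them in control, 25.5 ± 3.09% in Cx43-wt, 28.4 ± 2.0% in S282A and 27.1 ± 2.99% in the inhibitor group (SD, n = 4 each). In a gene of 1 kb, 3 reads were worth 0.167 to 0.218 FPKM, a floor for counting error only. Shorter genes read relatively higher in control 2, Cx43-wt 3, Cx43-wt 4 and inhibitor 4, where the slope of a library's log2 values on log2 gene length ran from -0.094 to -0.068. It ran from -0.014 to 0.075 in the other 12. These 4 are called the short-gene libraries, and Cx43-wt 4, Cx43-wt 5 and inhibitor 5 had the highest means of atrial genes. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these samples.

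Gja1 (ENSRNOG00000000805, Rnor_6.0 chromosome 20, 37876650 to 37889089), which encodes connexin 43, was measured first because the groups concern its protein. It stood at 156 ± 10.1 FPKM in control, 161 ± 27.4 in Cx43-wt, 147 ± 17.5 in S282A and 141 ± 27.7 in the inhibitor group (mean ± SD, n = 4 each). The S282A to Cx43-wt difference was -0.13, SE 0.14 (log2; adjusted p = 0.793). That difference changed sign with quantile normalization, without the short-gene libraries and without the 3 libraries highest in atrial genes. A gene total does not separate an introduced from the resident transcript, nor does it measure phosphorylation, so it did not test the labels. Dchs1, a protocadherin that binds Fat4 at the cell surface, had its highest mean in S282A, with 8.06 ± 0.354 FPKM in control, 7.64 ± 1.83 in Cx43-wt, 10.6 ± 1.63 in S282A and 7.08 ± 1.61 in the inhibitor group. Its difference was 0.43, SE 0.16 against Cx43-wt (adjusted p = 0.583), 0.34, SE 0.16 against control (adjusted p = 0.983) and -0.53, SE 0.16 for the inhibitor group against S282A (adjusted p = 0.619). Of 16 pairings of an S282A with a Cx43-wt library, 14 had the S282A value higher. Yap1, the coactivator that Hippo signalling restrains, stood at 40.4 ± 3.45 FPKM in control, 42.5 ± 4.20 in Cx43-wt, 44.7 ± 4.05 in S282A and 44.4 ± 3.14 in the inhibitor group. Lats1, the kinase that phosphorylates it, stood at 5.61 ± 0.341 FPKM in control, 5.54 ± 0.468 in Cx43-wt, 6.42 ± 0.665 in S282A and 6.12 ± 0.721 in the inhibitor group. Among the Tead factors, the DNA-binding partners of Yap1, Tead1 was most abundant at 24.7 ± 4.09 FPKM in control, 25.7 ± 2.02 in Cx43-wt, 23.9 ± 5.38 in S282A and 31.6 ± 5.60 in the inhibitor group. Its difference between the inhibitor group and S282A was 0.40, SE 0.16 (adjusted p = 0.631). Tead2, Tead3 and Tead4 differed between S282A and Cx43-wt by 0.068, 0.17 and 0.17. None of these 8 genes passed limma's test in any of the 5 comparisons, so no difference in them exceeded the spread between libraries after adjustment.

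**Figure D1:**
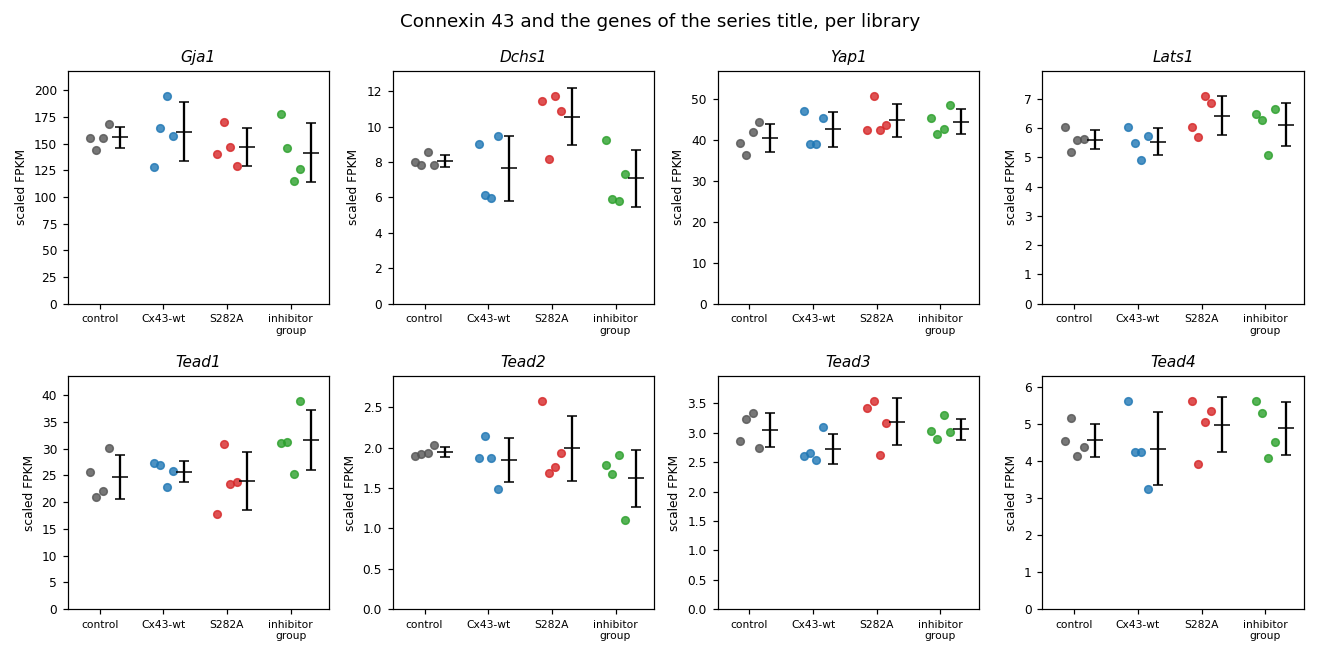
FPKM (vertical axes) of Gja1, Dchs1, Yap1, Lats1 and the Tead genes by group (horizontal axes), each point 1 library and each bar the mean with its SD, n = 4. Dchs1 averaged 10.6 FPKM in S282A and 7.64 in Cx43-wt, where the short-gene libraries Cx43-wt 3 and Cx43-wt 4 stood at 6.15 and 5.98. No gene shown passed the test in any comparison.

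S282A against Cx43-wt is the comparison the series' design text names, and asks what the exchange of the serine altered in heart tissue. Genes of fatty acid oxidation, the main source of energy of the adult heart, were lower in S282A. All 23 measured members had lower means, by an average log2 difference of -0.38 (library means 6.88 ± 0.17 against 7.26 ± 0.15, SD, n = 4 each). The list fell by camera (camera adjusted p = 1.07e-07, and adjusted p = 0.489 with an estimated correlation). They included Acsl1, which activates long-chain fatty acids (-0.37, 212 ± 20.1 against 273 ± 18.9 FPKM), and Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain (-0.36, 133 ± 15.9 against 172 ± 24.1 FPKM). The nuclear genes of oxidative phosphorylation fell too, 31 of 32 lower by an average of -0.29 (library means 8.51 ± 0.16 against 8.80 ± 0.35; camera adjusted p = 6.78e-07, and adjusted p = 0.633 with an estimated correlation). Uqcrc2, of respiratory complex III, stood at -0.31 and Cox6a2, a heart and muscle subunit of cytochrome oxidase, at -0.37. For the TCA cycle all 18 were lower (-0.17; camera adjusted p = 0.000288, and adjusted p = 0.633 with an estimated correlation). Among them were Suclg2 (-0.34) and Sucla2 (-0.31), subunits of succinate-CoA ligase. Ribosomal protein genes were lower for 25 of 27 (-0.29; camera adjusted p = 0.000726, and adjusted p = 0.647 with an estimated correlation). Rplp1 stood at -0.39 and Rpl7a at -0.76, with Rpl7a at 89.2 FPKM in Cx43-wt 3 and 18.1 to 22.2 in the other Cx43-wt libraries. The sarcomere list did not pass, with a mean of -0.12. Without the short-gene libraries the fatty acid oxidation call held at -0.28, and those of oxidative phosphorylation (-0.0051), TCA cycle (-0.061) and ribosomal proteins (-0.027) ended. With quantile normalization the calls of oxidative phosphorylation (-0.12), TCA cycle (-0.033) and ribosomal proteins (-0.14) ended. The call of ribosomal proteins (-0.17) ended with each library's length trend removed. With length slope and atrial mean as covariates the call of ribosomal proteins (-0.086) ended. The oxidative phosphorylation mean moved by over 1.5 times, its call kept, without Cx43-wt 3 (-0.16). Over the alternatives run for these lists, the adjusted p ranged from 4.86e-10 to 0.869.

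Vascular mural cell and matrix genes were higher in S282A than in Cx43-wt. Smooth muscle library means of S282A (4.86 to 5.06) lay within the control range (4.70 to 5.27). Most Cx43-wt means lay below it. Of the smooth muscle and pericyte list, all 12 members were higher, by 0.36 on average (library means 4.98 ± 0.088 against 4.62 ± 0.15, SD, n = 4 each; camera adjusted p = 9.49e-06, and adjusted p = 0.489 with an estimated correlation). Notch3, a receptor of vascular smooth muscle and pericytes, stood at 32.2 ± 1.80 against 21.4 ± 3.62 FPKM (log2 difference 0.58, SE 0.15), and Pdgfrb, the growth factor receptor that marks pericytes, at 36.3 ± 2.99 against 26.7 ± 4.08 FPKM (0.44, SE 0.13). Adjusted over the list alone, 3 members of the smooth muscle list passed (Notch3, Pdgfrb and Cspg4), where 0 did over all genes tested. In this comparison 0 members of the other lists passed over their list alone. These passes were not adjusted over the 36 lists, so they could arise by chance. Collagen and matrix genes were higher for 24 of 25 (0.38; library means 5.53 ± 0.19 against 5.15 ± 0.67; camera adjusted p = 4.48e-06, and adjusted p = 0.633 with an estimated correlation). The collagen chains Col6a2 (0.45) and Col5a1 (0.56) were among them. Matrix proteases and their inhibitors were higher for all 15 (0.24; camera adjusted p = 0.000913, and adjusted p = 0.489 with an estimated correlation). The metalloproteinases Mmp15 and Mmp23 stood at 0.33 and 0.32. TGF-beta signalling genes were higher for 21 of 25 (0.17; camera adjusted p = 0.000726, and adjusted p = 0.489 with an estimated correlation). The cytokine Tgfb1 stood at 0.34 and its coreceptor Tgfbr3 at 0.32. Myofibroblast markers were higher for 11 of 12 (0.46; camera adjusted p = 0.0155, and adjusted p = 0.633 with an estimated correlation). Runx1 stood at 0.29 and Comp at 1.34, with Comp at 7.54 FPKM in Cx43-wt 5 and 0.210 to 1.22 in the other Cx43-wt libraries. Leaving out the short-gene libraries, the smooth muscle call held, and those of matrix (-0.077), matrix proteases (0.040), TGF-beta (-0.020) and myofibroblast (0.16) ended. The call of myofibroblast (0.41) ended at a mean of at least 5 FPKM. The TGF-beta call ended without Cx43-wt 3 (0.086) and the myofibroblast call without Cx43-wt 1 (0.45), Cx43-wt 3 (0.33), S282A 4 (0.35) or S282A 7 (0.36). The matrix mean moved by over 1.5 times, its call kept, without Cx43-wt 3 (0.14) or Cx43-wt 5 (0.68) and the matrix proteases mean without Cx43-wt 3 (0.15). The adjusted p of these lists ranged from 2.91e-19 to 0.979 over their alternatives.

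Hippo pathway components were higher in S282A for 28 of 35 members, by a small average of 0.089 (library means 3.42 ± 0.026 against 3.33 ± 0.064, SD, n = 4 each). The list rose by camera (camera adjusted p = 0.000726, and adjusted p = 0.489 with an estimated correlation). Besides Dchs1, Csnk1e, a casein kinase of the pathway, stood at 0.20 (17.8 ± 0.951 against 15.4 ± 1.43 FPKM). The YAP/TEAD target list was higher for 16 of 21 (0.12; camera adjusted p = 0.0159, and adjusted p = 0.489 with an estimated correlation). The coagulation receptor F3 stood at 0.45 and the receptor kinase Axl at 0.40, and 5 genes stand in both lists. The study named the Hippo pathway from these samples, so its list is not independent evidence of direction. Adjusted over the list alone, 0 Hippo members passed, as over all genes. Across the 16 libraries the Hippo mean followed the length slope (Pearson r = 0.906, two-sided permutation p = 4e-05; Spearman rho = 0.785, two-sided permutation p = 0.00059). The Benjamini-Hochberg values were 0.00012 and 0.00177 over 6 relations computed. Without the 2 libraries farthest in slope r was 0.841, and with group means removed it was 0.936. Without the short-gene libraries neither call held, at 0.035 for Hippo and 0.034 for YAP/TEAD targets. With the replicate number as a block, where the S282A side rested on S282A 1 and S282A 4, the call of YAP/TEAD targets (0.067) ended. The call of YAP/TEAD targets (0.10) ended with each library's length trend removed. With length slope and atrial mean as covariates the calls of Hippo (0.041) and YAP/TEAD targets (0.093) ended. The YAP/TEAD targets call ended without Cx43-wt 3 (0.072) or S282A 7 (0.081). Over their alternatives the adjusted p ranged from 0.000404 to 0.686. Gap junction and intercalated disc genes did not pass (12 of 15 higher, 0.056, camera adjusted p = 0.155). Gja4, a connexin of vessel endothelium, stood at 0.34 and Ctnnb1, beta-catenin, at 0.20.

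Red cell, endothelial and glucocorticoid-responsive genes were higher in S282A and atrial genes lower. Erythroid genes were higher for all 8 (0.76; camera adjusted p = 0.0155, and adjusted p = 0.633 with an estimated correlation). The anion exchanger Slc4a1 stood at 1.07 and the globin Hba-a3 at 1.43. Endothelial genes were higher for 9 of 11 (0.17; camera adjusted p = 0.0155, and adjusted p = 0.633 with an estimated correlation). The cadherin Cdh5 (0.31) and the VEGF receptor Flt1 (0.36) were among them. Glucocorticoid-responsive genes were higher for 8 of 12 (0.31; camera adjusted p = 0.0430, and adjusted p = 0.633 with an estimated correlation). Per1, also a clock gene, stood at 1.46 and Errfi1 at 1.03. Atrial markers were lower for 8 of 9 (-0.60; library means 4.24 ± 1.15 against 4.84 ± 2.11, SD, n = 4 each; camera adjusted p = 0.0193, and adjusted p = 0.633 with an estimated correlation). Kcnj3, a potassium channel subunit of the atria, stood at -0.43. Bmp10, an atrial growth factor, stood at 57.8 FPKM in Cx43-wt 4 and 10.6 in Cx43-wt 5, but at 0 and 0.0445 in Cx43-wt 1 and Cx43-wt 3, within the S282A range of 0 to 0.0970. With the replicate number as a block, where the S282A side rested on S282A 1 and S282A 4, the calls of erythroid (0.044), endothelial (0.073) and atrial (-0.10) ended. The call of glucocorticoid (0.34) ended with library weights. At a mean of at least 5 FPKM the calls of erythroid (0.77) and atrial (-0.38) ended. The call of glucocorticoid (0.31) ended with only the libraries of both groups. The erythroid call ended without Cx43-wt 5 (0.68) or S282A 6 (0.47) and the endothelial call without Cx43-wt 5 (0.070) or S282A 1 (0.11). The glucocorticoid call ended without control 2 (0.31), Cx43-wt 3 (0.29), Cx43-wt 4 (0.23), Cx43-wt 5 (0.20), S282A 1 (0.20), S282A 4 (0.28), S282A 7 (0.32) or inhibitor 5 (0.31) and the atrial call without Cx43-wt 4 (0.10), Cx43-wt 5 (-0.088) or S282A 6 (-0.038). The glucocorticoid mean moved by over 1.5 times, its call kept, without Cx43-wt 1 (0.52) and the atrial mean without Cx43-wt 1 (-1.15), Cx43-wt 3 (-1.26) or S282A 4 (-0.91). In the fit without Cx43-wt 4 the atrial mean and camera's direction differed in sign. Without the 3 libraries highest in atrial genes the calls of endothelial (0.015), glucocorticoid (0.017) and atrial (1.22) ended, and without the short-gene libraries that of glucocorticoid (0.16). The adjusted p of these lists ranged from 1.95e-05 to 0.830 over their alternatives.

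Among the genes nearest to passing in this comparison were Colgalt2, a collagen galactosyltransferase (7.27 ± 0.660 against 4.77 ± 0.557 FPKM; 0.52, SE 0.10), the membrane semaphorin Sema7a (0.57, SE 0.14) and the actin crosslinker Actn4 (0.35, SE 0.089) on the side higher in S282A. On the lower side were Ehhadh, a fatty acid oxidation enzyme of peroxisomes (-0.48, SE 0.10), and the splicing factor Snrpd1 (-0.52, SE 0.11). Each had an adjusted p = 0.583, and the libraries of both groups did not overlap for any of these 5. No single gene passed an adjusted p of 0.05 by limma, with a smallest adjusted p of 0.583 over 12935 genes, and voom on the recovered reads also called 0. At an unadjusted p under 0.05, 1105 genes differed, 507 higher and 598 lower, where 647 would by chance. That count was 1753 without Cx43-wt 1, 589 without Cx43-wt 3, 510 without Cx43-wt 4 and 1686 without Cx43-wt 5. The libraries of both groups did not overlap for 3.58% of genes, against 2.86% by chance. Of 36 lists, 15 passed camera at its preset correlation, 10 upward and 5 downward, and 0 with an estimated correlation or by fry. The spread allowed a median SE of 0.14 on the log2 scale, so 2 SE for the median gene came to a 1.21-fold difference.

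**Figure D2:**
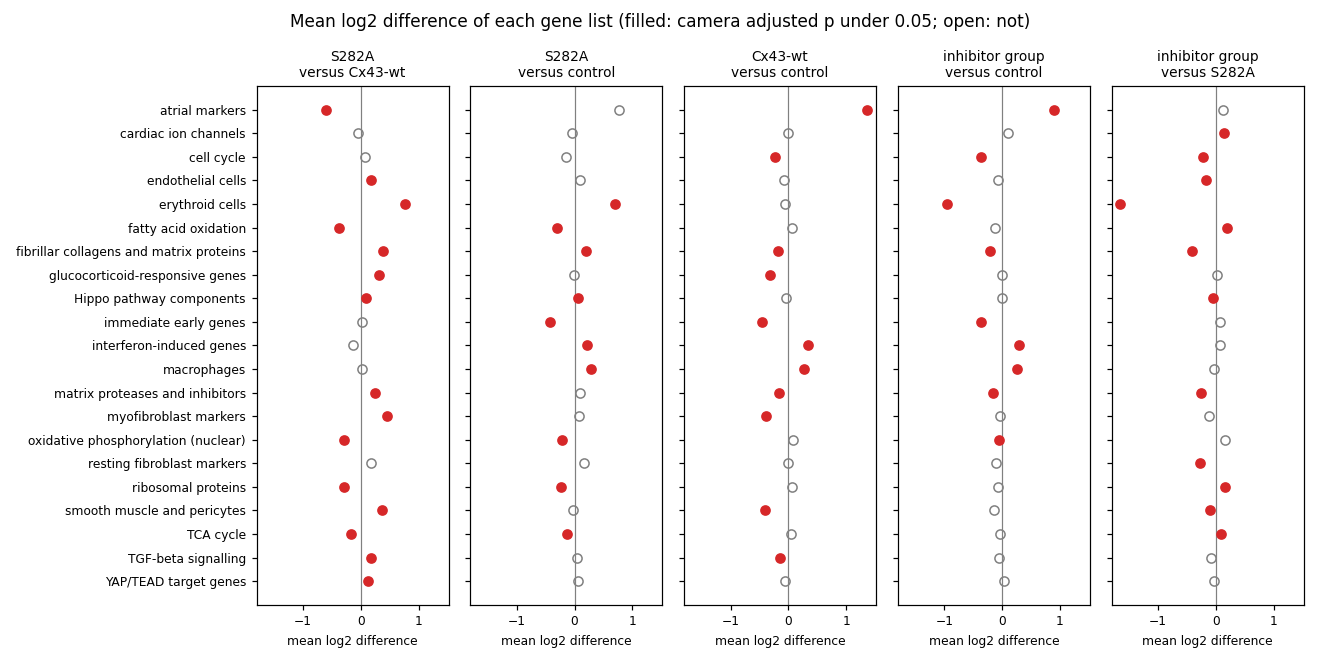
Mean log2 difference (horizontal axis) of the gene lists (vertical axis) in each comparison, with filled points for lists past the camera threshold at its preset correlation. In S282A against Cx43-wt, fatty acid oxidation stands at -0.38 and matrix genes at 0.38, and 0 lists pass with an estimated correlation.

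S282A against control asks how the mutant connexin heart differs from the control heart. Fatty acid oxidation genes were lower in S282A for all 23 members (-0.31; library means 6.88 ± 0.17 against 7.19 ± 0.24, SD, n = 4 each). The list fell by camera (camera adjusted p = 3.93e-09, and adjusted p = 0.834 with an estimated correlation), and with the replicate number as a block that call ended (-0.15, adjusted p = 0.0592). Hadhb, a subunit of the trifunctional enzyme, stood at 522 ± 66.5 against 664 ± 58.1 FPKM (-0.35, SE 0.13). Oxidative phosphorylation genes were lower for 31 of 32 (-0.22; camera adjusted p = 3.91e-05, and adjusted p = 0.834 with an estimated correlation), with Cox6a2 at -0.29. TCA cycle genes were lower for 16 of 18 (-0.13; camera adjusted p = 0.00148, and adjusted p = 0.834 with an estimated correlation), with Suclg2 at -0.29. Ribosomal protein genes were lower for 22 of 27 (-0.23; camera adjusted p = 0.0267, and adjusted p = 0.834 with an estimated correlation), with Rplp1 at -0.40. Immediate early genes, which cells switch on within minutes of a stimulus, were lower for 15 of 17 (-0.43; camera adjusted p = 0.000941, and adjusted p = 0.834 with an estimated correlation). Ier3 stood at 9.79 ± 1.15 against 14.8 ± 1.83 FPKM (-0.55). Macrophage markers were higher for 12 of 14 (0.28; camera adjusted p = 0.000144, and adjusted p = 0.834 with an estimated correlation). The lysosomal glycoprotein Cd68 stood at 7.01 ± 0.614 against 5.03 ± 0.710 FPKM (0.41). Interferon-induced genes were higher for 20 of 23 (0.21; library means 3.36 ± 0.19 against 3.15 ± 0.056; camera adjusted p = 0.000195, and adjusted p = 0.834 with an estimated correlation), with the chemokine Cxcl10 at 0.66. Matrix genes were higher for 22 of 25 (0.21; camera adjusted p = 0.00541, and adjusted p = 0.834 with an estimated correlation), with the collagen chain Col8a1 at 0.53. Erythroid genes were higher for all 8 (0.69; camera adjusted p = 0.0196, and adjusted p = 0.834 with an estimated correlation). Alas2, the first enzyme of erythroid haem synthesis, stood at 1.07. Hippo components were higher for 26 of 35 (0.051; camera adjusted p = 0.0151, and adjusted p = 0.834 with an estimated correlation), again in a list the study named from these samples. Fat4, the receptor of Dchs1, stood at 0.30 and Dchs1 at 0.34. YAP/TEAD targets (F3 0.44), smooth muscle genes, myofibroblast markers (Runx1 0.21) and gap junction genes (Tjp1 0.16) did not pass. With quantile normalization the calls of TCA cycle (-0.054) and ribosomal proteins (-0.15) ended. The calls of fatty acid oxidation (-0.15), oxidative phosphorylation (-0.051), TCA cycle (-0.091), ribosomal proteins (-0.11), interferon (0.13), matrix (0.013), erythroid (-0.21) and Hippo (0.016) ended with the replicate number as a block. In that setting the S282A side rested on S282A 1 and S282A 4, as no other group held the numbers 6 and 7. With each library's length trend removed the calls of ribosomal proteins (-0.18) and Hippo (0.028) ended. The calls of ribosomal proteins (-0.16), matrix (-0.0035) and Hippo (0.030) ended with length slope and atrial mean as covariates. At a mean of at least 5 FPKM the call of ribosomal proteins (-0.23) ended. The ribosomal proteins call ended without control 2 (-0.12), control 4 (-0.23), S282A 4 (-0.17) or S282A 6 (-0.18) and the immediate early call without control 4 (-0.22) or S282A 1 (-0.27). The matrix call ended without control 1 (0.13), control 3 (0.14) or S282A 7 (0.12) and the erythroid call without control 2 (0.49), control 4 (0.67) or S282A 6 (0.40). The Hippo call ended without control 2 (0.028). The TCA cycle mean moved by over 1.5 times, its call kept, without S282A 4 (-0.20) and the macrophage mean without control 1 (0.18) or control 3 (0.19). The matrix mean likewise moved without control 2 (0.31). Without the short-gene libraries, of which control 2 was the only one here, the calls of ribosomal proteins (-0.12), erythroid (0.49) and Hippo (0.028) ended. Over the alternatives run for these lists the adjusted p ran from 1.07e-13 to 0.986.

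The single genes nearest to passing were the adaptor Sla (0.43, SE 0.11), Asna1, an ATPase of membrane protein insertion (0.54, SE 0.15), and Retnlg, a resistin-like gene (1.39, SE 0.39), higher in S282A. The Mediator subunit Med20 (-0.32, SE 0.066), the phosphodiesterase Smpdl3a (-0.61, SE 0.13) and the histone variant H2afx (-0.49, SE 0.12) were lower. Each had an adjusted p = 0.983. No single gene passed an adjusted p of 0.05 by limma, with a smallest adjusted p of 0.983 over 12935 genes, and voom on the recovered reads also called 0. At an unadjusted p under 0.05, 539 genes differed, 238 higher and 301 lower, where 647 would by chance. That count was 344 without S282A 7. The libraries of both groups did not overlap for 3.39% of genes, against 2.86% by chance. Of 36 lists, 10 passed camera at its preset correlation, 5 upward and 5 downward, and 0 with an estimated correlation or by fry. Adjusted over the list alone, 0 members of any list passed in this comparison.

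Cx43-wt against control asks how the normal connexin hearts differed from the control hearts. The labels do not say what the control received, so an effect of the connexin cannot be told apart from one of its delivery. Interferon-induced genes were higher in Cx43-wt for all 23 members (0.34; library means 3.49 ± 0.29 against 3.15 ± 0.056, SD, n = 4 each). The list rose by camera (camera adjusted p = 6.90e-09, and adjusted p = 0.490 with an estimated correlation). Oasl, an antiviral oligoadenylate synthetase-like gene, stood at 1.90 ± 0.433 against 1.03 ± 0.273 FPKM (0.52, SE 0.18). Macrophage markers were higher for 12 of 14 (0.27; camera adjusted p = 1.39e-05, and adjusted p = 0.546 with an estimated correlation). The complement gene C1qa stood at 42.5 ± 7.55 against 28.7 ± 8.17 FPKM (0.57). Atrial markers were higher for all 9 (1.37; library means 4.84 ± 2.11 against 3.47 ± 1.23; camera adjusted p = 6.37e-06, and adjusted p = 0.490 with an estimated correlation). Kcnj3 stood at 16.3 ± 4.38 against 10.2 ± 1.52 FPKM (0.60, SE 0.16) and was the 1 member of any list that passed when adjusted over its list alone, while over all genes 0 did. That pass was not adjusted over the 36 lists and could arise by chance. Smooth muscle and pericyte genes were lower for all 12 (-0.40; library means 4.62 ± 0.15 against 5.01 ± 0.24; camera adjusted p = 4.40e-07, and adjusted p = 0.340 with an estimated correlation). Myh11, the smooth muscle myosin, stood at 18.3 ± 3.59 against 39.1 ± 22.7 FPKM (-0.91, SE 0.36). Immediate early genes were lower for 16 of 17 (-0.45; camera adjusted p = 4.05e-08, and adjusted p = 0.490 with an estimated correlation), with the transcription factor Klf6 at -0.48. Cell cycle genes were lower for 17 of 21 (-0.23; camera adjusted p = 0.000158, and adjusted p = 0.598 with an estimated correlation), with the mitotic cyclin Ccnb1 at -0.46. Genes of TGF-beta signalling were lower for 22 of 25 (-0.14; camera adjusted p = 0.00285, and adjusted p = 0.546 with an estimated correlation), with its inhibitor Smad7 at -0.19. Glucocorticoid-responsive genes were lower for 9 of 12 (-0.33; camera adjusted p = 0.00572, and adjusted p = 0.546 with an estimated correlation), with the kinase Sgk1 at -0.96. Matrix genes were lower for 22 of 25 (-0.17; camera adjusted p = 0.00747, and adjusted p = 0.626 with an estimated correlation), with the collagen crosslinker Lox at -0.49. Matrix proteases were lower for 13 of 15 (-0.15; camera adjusted p = 0.0102, and adjusted p = 0.546 with an estimated correlation), with Mmp23 at -0.33. Myofibroblast markers were lower for 9 of 12 (-0.38; camera adjusted p = 0.0102, and adjusted p = 0.598 with an estimated correlation). The smooth muscle actin Acta2 stood at 55.8 ± 6.86 against 156 ± 133 FPKM (-1.13). Hippo components (-0.038, camera adjusted p = 0.106; Stk3 0.21, Fjx1 -0.27), YAP/TEAD targets (-0.057, camera adjusted p = 0.134) and gap junction genes (Gja4 -0.29) did not pass.

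Several of these Cx43-wt calls rested on few libraries. The cell cycle call ended without control 2 (-0.087) and the TGF-beta call without Cx43-wt 3 (-0.052). The glucocorticoid call ended without control 2 (-0.25) or Cx43-wt 5 (-0.21) and the matrix call without control 2 (-0.068), Cx43-wt 3 (0.061) or Cx43-wt 4 (-0.11). The matrix proteases call ended without control 2 (-0.12), Cx43-wt 3 (-0.059) or Cx43-wt 4 (-0.12) and the myofibroblast call without control 2 (-0.042), control 4 (-0.32), Cx43-wt 3 (-0.25) or Cx43-wt 4 (-0.32). The immediate early mean moved by over 1.5 times, its call kept, without control 4 (-0.23) and the atrial mean without Cx43-wt 4 (0.67) or Cx43-wt 5 (0.86). The macrophage mean likewise moved without control 1 (0.17), control 3 (0.17) or Cx43-wt 5 (0.16) and the TGF-beta mean without Cx43-wt 5 (-0.22). The glucocorticoid mean likewise moved without Cx43-wt 1 (-0.54) and the matrix mean without Cx43-wt 5 (-0.47). The matrix proteases mean likewise moved without Cx43-wt 5 (-0.24) and the myofibroblast mean without control 3 (-0.64) or Cx43-wt 5 (-0.59). The call of glucocorticoid (-0.26) ended with the replicate number as a block. Leaving out the short-gene libraries, the calls of immediate early (-0.13), cell cycle (0.026), TGF-beta (0.067), glucocorticoid (-0.11), matrix (0.39), matrix proteases (0.078) and myofibroblast (0.25) ended or turned. That left 2 Cx43-wt libraries, and matrix genes were then higher by camera (adjusted p = 6.85e-07, and 0.740 with an estimated correlation). Only Cx43-wt 5 (6.04) lay above the other controls, at 5.09 to 5.44, and Cx43-wt 1 (5.18) lay among them. Without the 3 libraries highest in atrial genes the calls of atrial (-0.45), macrophage (0.12) and glucocorticoid (-0.033) ended. Over the alternatives run for these lists the adjusted p ran from 6.83e-16 to 0.905. Nearest to passing among single genes were Kcnj3, the mast cell protease-like gene Mcpt1l1 (0.98, SE 0.27) and the SNARE protein Stx8 (0.46, SE 0.13), higher in Cx43-wt. The checkpoint gene Rad9a (-0.34, SE 0.091), the alcohol dehydrogenase Adh1 (-0.90, SE 0.24) and the phosphatase Dusp2 (-0.65, SE 0.19) were nearest among those lower, all 6 with an adjusted p = 1.000. No single gene passed an adjusted p of 0.05 by limma, with a smallest adjusted p of 1.000 over 12935 genes, and voom on the recovered reads also called 0. At an unadjusted p under 0.05, 360 genes differed, 205 higher and 155 lower, where 647 would by chance. That count was 563 without control 2, 688 without Cx43-wt 1 and 647 without Cx43-wt 5. The libraries of both groups did not overlap for 1.51% of genes, against 2.86% by chance. Of 36 lists, 11 passed camera at its preset correlation, 3 upward and 8 downward, and 0 with an estimated correlation or by fry.

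**Figure D3:**
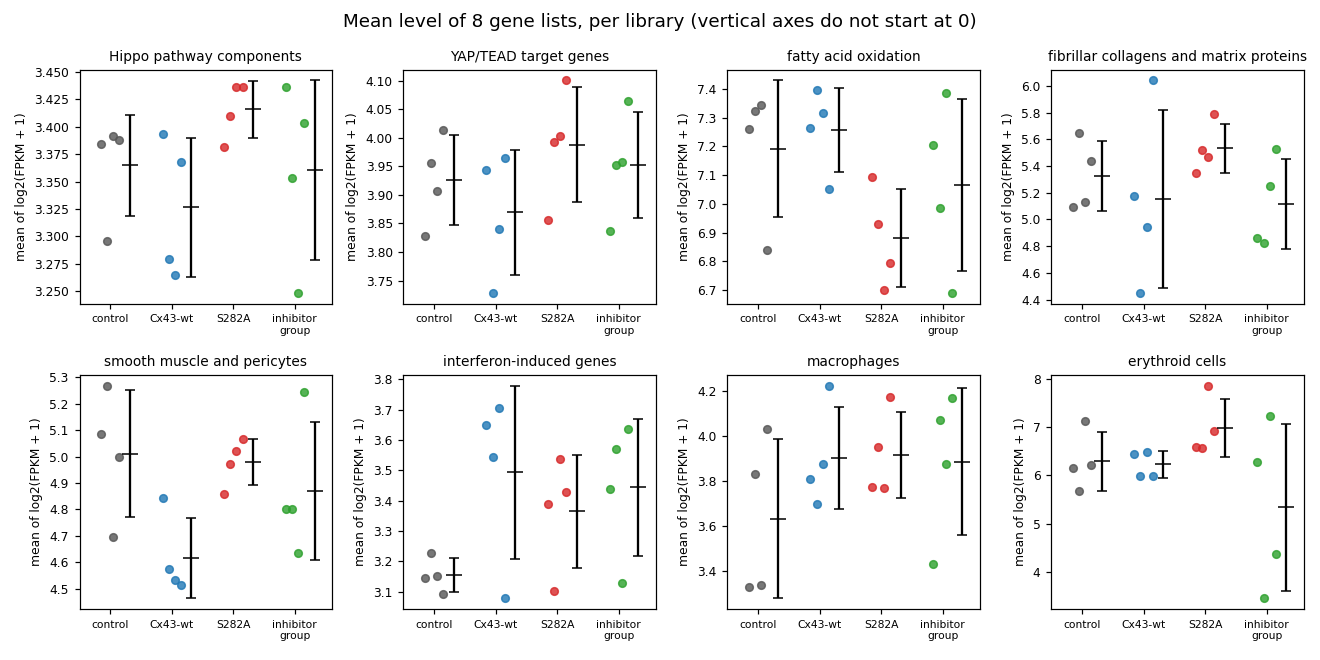
Mean log2(FPKM + 1) over the members of selected lists (vertical axes) in each library by group (horizontal axes), with bars for the group mean and its SD, n = 4. Interferon-induced genes averaged 3.15 in control and 3.49 in Cx43-wt, and Hippo components 3.36 and 3.33.

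The inhibitor group against control asks what the agent named in the labels altered. Cell cycle genes were lower in the inhibitor group for 18 of 21 members (-0.37; library means 1.48 ± 0.34 against 1.85 ± 0.30, SD, n = 4 each). The list fell by camera (camera adjusted p = 2.09e-05, and adjusted p = 0.933 with an estimated correlation). The proliferation marker Mki67 stood at 0.869 ± 0.737 against 2.14 ± 0.909 FPKM (-0.79, SE 0.28). Interferon-induced genes were higher for 21 of 23 (0.29; library means 3.44 ± 0.23 against 3.15 ± 0.056; camera adjusted p = 5.54e-05, and adjusted p = 0.933 with an estimated correlation). Irf7, the regulator of type I interferon, stood at 37.1 ± 11.8 against 19.2 ± 2.88 FPKM (0.86, SE 0.25). Macrophage markers were higher for 11 of 14 (0.25; camera adjusted p = 0.00896, and adjusted p = 0.933 with an estimated correlation). Gpnmb, a glycoprotein of activated macrophages, stood at 13.0 ± 3.28 against 7.48 ± 1.45 FPKM (0.71, SE 0.17). Atrial markers were higher for all 9 (0.89; library means 4.37 ± 0.93 against 3.47 ± 1.23; camera adjusted p = 0.00836, and adjusted p = 0.933 with an estimated correlation). Kcnj3 stood at 18.4 ± 1.53 against 10.2 ± 1.52 FPKM (0.80, SE 0.16). Adjusted over the list alone, Gpnmb and Kcnj3 passed in their lists and 0 members of other lists did, and over all genes 0 did. Both passes were without adjustment over the 36 lists and could arise by chance. Erythroid genes were lower for all 8 (-0.96; library means 5.33 ± 1.73 against 6.29 ± 0.61; camera adjusted p = 0.00521, and adjusted p = 0.933 with an estimated correlation), with the globin Hba-a2 at -1.27. Matrix genes were lower for 21 of 25 (-0.21; camera adjusted p = 0.00836, and adjusted p = 0.934 with an estimated correlation), with the crosslinking enzyme Loxl1 at -0.66. Immediate early genes were lower for 13 of 17 (-0.36; camera adjusted p = 0.0148, and adjusted p = 0.933 with an estimated correlation), with Klf6 at -0.43. Matrix proteases were lower for 11 of 15 (-0.16; camera adjusted p = 0.0195, and adjusted p = 0.933 with an estimated correlation), with the shedding protease Adam17 at -0.34. Oxidative phosphorylation genes were lower for 27 of 32 (-0.062; camera adjusted p = 0.0148, and adjusted p = 0.934 with an estimated correlation), with Cox5b at -0.50. Hippo components went both ways, 19 higher and 16 lower, and did not pass (mean -0.0046, median 0.0070, camera adjusted p = 0.914). Their mean and median differed in sign, and Fjx1 stood at -0.38 and Tead1 at 0.34. YAP/TEAD targets, myofibroblast markers (Fap -0.40) and gap junction genes (Dsp 0.33) did not pass either.

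Cell cycle and interferon were the lists whose calls against control stood without any 1 of the 16 libraries. The cell cycle difference lay mostly in inhibitor 2 and inhibitor 5, with list means of 1.23 and 1.200. Those of inhibitor 1 and inhibitor 4 were 1.56 and 1.92, near and within the control range of 1.61 to 2.29. Inhibitor 2 and inhibitor 5 also had the lowest erythroid means of all libraries (3.45 and 4.38, the others 5.67 to 7.86), so both lists were low in the same libraries. The interferon mean of inhibitor 4 (3.13) lay within the control range of 3.09 to 3.23. The erythroid call ended without control 3 (-0.68), inhibitor 2 (-0.33) or inhibitor 5 (-0.64) and the atrial call without control 1 (0.52) or inhibitor 5 (0.60). The matrix call ended without control 2 (-0.10), inhibitor 1 (-0.13) or inhibitor 2 (-0.11) and the macrophage call without control 1 (0.15), control 3 (0.16), inhibitor 2 (0.19), inhibitor 4 (0.26) or inhibitor 5 (0.16). The oxidative phosphorylation call ended without control 1 (-0.036), control 2 (-0.023), inhibitor 2 (-0.024) or inhibitor 5 (-0.028) and the immediate early call without control 4 (-0.14), inhibitor 1 (-0.34), inhibitor 2 (-0.24) or inhibitor 5 (-0.31). The matrix proteases call ended without control 2 (-0.13), inhibitor 2 (-0.12) or inhibitor 4 (-0.17). The cell cycle mean moved by over 1.5 times, its call kept, without control 2 (-0.23) and the erythroid mean without inhibitor 4 (-1.59). The atrial mean likewise moved without control 2 (1.35) or control 3 (0.57) and the matrix mean without inhibitor 5 (-0.35). The macrophage mean likewise moved without control 4 (0.39) or inhibitor 1 (0.41) and the oxidative phosphorylation mean without control 3 (-0.11), inhibitor 1 (-0.023) or inhibitor 4 (-0.17). The immediate early mean likewise moved without inhibitor 4 (-0.54). The call of oxidative phosphorylation (0.0037) ended with quantile normalization. With the replicate number as a block the calls of atrial (0.13), macrophage (0.10) and oxidative phosphorylation (0.036) ended. The calls of macrophage (0.14) and oxidative phosphorylation (0.015) ended with length slope and atrial mean as covariates. At a mean of at least 5 FPKM the calls of immediate early (-0.34) and matrix proteases (-0.15) ended. Leaving out the short-gene libraries, the calls of matrix (-0.15) and matrix proteases (-0.14) ended. Without the 3 libraries highest in atrial genes those of erythroid (-0.64), macrophage (0.16), oxidative phosphorylation (-0.028) and immediate early (-0.31) did. Their adjusted p ran from 3.74e-16 to 1.00 over the alternatives. Kcnj3, Mllt6 (0.40, SE 0.079) and Sla (0.52, SE 0.11) were nearest to passing among genes higher in the inhibitor group. The adrenergic receptor Adra1d (-0.84, SE 0.18), Kazald1 (-0.75, SE 0.17) and Chchd4, of mitochondrial import (-0.77, SE 0.18), were nearest among those lower, all 6 with an adjusted p = 0.903. No single gene passed an adjusted p of 0.05 by limma, with a smallest adjusted p of 0.903 over 12935 genes, and voom on the recovered reads also called 0. At an unadjusted p under 0.05, 671 genes differed, 333 higher and 338 lower, where 647 would by chance. That count was 369 without inhibitor 2 and 1485 without inhibitor 4. The libraries of both groups did not overlap for 2.71% of genes, against 2.86% by chance. Of 36 lists, 9 passed camera at its preset correlation, 3 upward and 6 downward, and 0 with an estimated correlation or by fry.

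**Figure D4:**
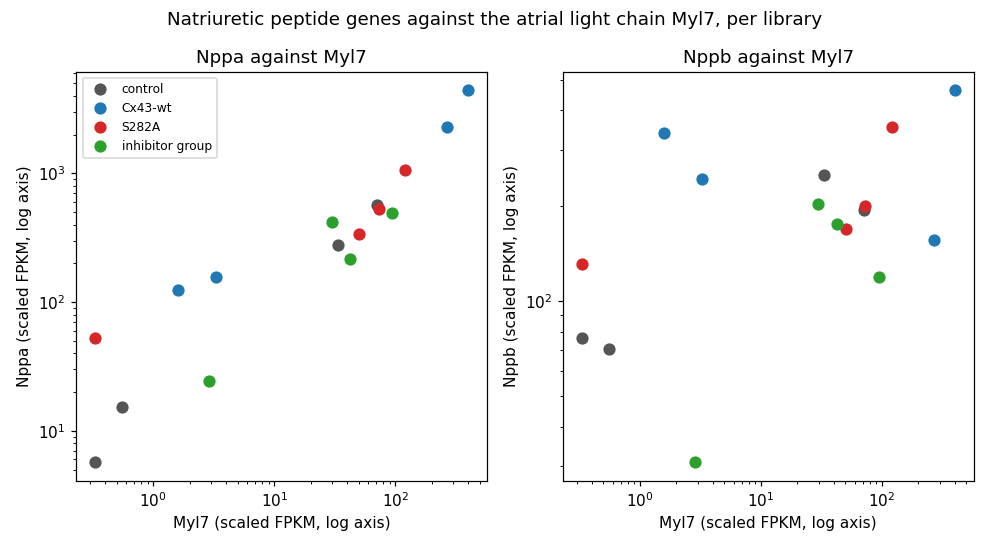
FPKM of the natriuretic peptide genes Nppa (left, vertical axis) and Nppb (right, vertical axis) against that of the atrial myosin light chain gene Myl7 (horizontal axes) on log axes. Each of the 16 points is 1 library, coloured by group. Nppa ran from 5.71 FPKM in control 1 to 4411 in Cx43-wt 4, and Myl7 from 0.331 to 401.

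The inhibitor group against S282A asks what differed between these hearts, whose relation the labels do not state. Matrix genes were lower in the inhibitor group for 24 of 25 members (-0.42; library means 5.12 ± 0.34 against 5.53 ± 0.19, SD, n = 4 each). The list fell by camera (camera adjusted p = 3.14e-07, and adjusted p = 0.743 with an estimated correlation). The collagen chain Col6a1 stood at 95.9 ± 13.2 against 129 ± 14.4 FPKM (-0.43, SE 0.14). Erythroid genes were lower for all 8 (-1.65; library means 5.33 ± 1.73 against 6.99 ± 0.61; camera adjusted p = 8.32e-07, and adjusted p = 0.743 with an estimated correlation). Alas2 stood at 8.99 ± 9.23 against 28.7 ± 16.8 FPKM (-2.10, SE 0.65). Matrix proteases were lower for 14 of 15 (-0.25; camera adjusted p = 0.000587, and adjusted p = 0.743 with an estimated correlation). Adam17 stood at -0.41, SE 0.12 and Mmp15 at -0.49, SE 0.15. Resting fibroblast markers were lower for 8 of 11 (-0.27; camera adjusted p = 0.0235, and adjusted p = 0.749 with an estimated correlation). Cd34 stood at -0.46, SE 0.14 and Col15a1 at -1.23, SE 0.38. Adjusted over the list alone, 5 erythroid, 2 protease (Adam17, Mmp15), 2 resting fibroblast (Cd34, Col15a1) and 1 atrial member (Kcnj3) passed, with 0 of the other lists and 0 over all genes. As these passes were not adjusted over the 36 lists, some could arise by chance. Fatty acid oxidation genes were higher for 21 of 23 (0.19; camera adjusted p = 0.00107, and adjusted p = 0.749 with an estimated correlation). Hadhb stood at 676 ± 55.5 against 522 ± 66.5 FPKM (0.38, SE 0.13). TCA cycle genes were higher for 15 of 18 (0.10; camera adjusted p = 0.0269, and adjusted p = 0.749 with an estimated correlation), with Suclg2 at 0.28. Ribosomal protein genes were higher for 22 of 27 (0.16; camera adjusted p = 0.0232, and adjusted p = 0.749 with an estimated correlation), with Rplp1 at 0.42. Cardiac ion channels were higher for 15 of 18 (0.15; camera adjusted p = 0.0211, and adjusted p = 0.743 with an estimated correlation), with Cacna1c, the pore of the L-type calcium channel, at 0.32. Hippo components were lower for 27 of 35 (-0.055; library means 3.36 ± 0.082 against 3.42 ± 0.026; camera adjusted p = 0.0232, and adjusted p = 0.743 with an estimated correlation), in the list the study named. Dchs1 stood at -0.53 and Tead1, opposite, at 0.40. Cell cycle genes were lower for 18 of 21 (-0.22; camera adjusted p = 0.0196, and adjusted p = 0.749 with an estimated correlation), with Mki67 at -0.51. Endothelial genes were lower for 9 of 11 (-0.17; camera adjusted p = 0.0232, and adjusted p = 0.743 with an estimated correlation), with the VEGF receptor Kdr at -0.43. Smooth muscle genes were lower for 9 of 12 (-0.11; camera adjusted p = 0.0232, and adjusted p = 0.743 with an estimated correlation), with Pdgfrb at -0.33. YAP/TEAD targets (Gadd45b 0.88), myofibroblast markers (Fap -0.49) and gap junction genes (Gja4 -0.21) did not pass.

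Erythroid, matrix and protease calls against S282A stood without any 1 of the 16 libraries. The erythroid difference lay mostly in inhibitor 2 and inhibitor 5. The means of inhibitor 1 and inhibitor 4 were 6.28 and 7.23, near and within the S282A range of 6.58 to 7.86. The fatty acid oxidation call ended without inhibitor 4 (0.079) and the cell cycle call without S282A 6 (-0.16), inhibitor 2 (-0.14) or inhibitor 5 (-0.13). The ion channels call ended without S282A 1 (0.11) or inhibitor 5 (0.11) and the Hippo call without S282A 6 (-0.049), S282A 7 (-0.049) or inhibitor 4 (-0.018). The endothelial call ended without S282A 1 (-0.11), S282A 6 (-0.16), S282A 7 (-0.16), inhibitor 4 (-0.16) or inhibitor 5 (-0.14) and the smooth muscle call without S282A 6 (-0.10), S282A 7 (-0.081) or inhibitor 4 (-0.030). The ribosomal proteins call ended without S282A 4 (0.10), S282A 6 (0.11), S282A 7 (0.18), inhibitor 2 (0.12) or inhibitor 4 (0.026) and the resting fibroblast call without S282A 1 (-0.27), S282A 7 (-0.23), inhibitor 1 (-0.21) or inhibitor 4 (-0.32). The TCA cycle call ended without S282A 1 (0.076), S282A 6 (0.077), S282A 7 (0.070), inhibitor 1 (0.082) or inhibitor 4 (0.055). The erythroid mean moved by over 1.5 times, its call kept, without inhibitor 2 (-1.02) and the fatty acid oxidation mean without inhibitor 5 (0.31). The cell cycle mean likewise moved without inhibitor 4 (-0.37) and the smooth muscle mean without inhibitor 5 (-0.23). The ribosomal proteins mean likewise moved without S282A 1 (0.24) or inhibitor 1 (0.30) and the TCA cycle mean without S282A 4 (0.17). With quantile normalization the calls of cell cycle (-0.17) and TCA cycle (0.075) ended. The calls of erythroid (-0.49), cell cycle (-0.16), ion channels (0.15), Hippo (-0.036), endothelial (-0.045), smooth muscle (-0.12) and ribosomal proteins (0.073) ended with the replicate number as a block. In that setting the S282A side rested on S282A 1 and S282A 4. With length slope and atrial mean as covariates the call of Hippo (-0.048) ended. The calls of Hippo (-0.044), endothelial (-0.17), smooth muscle (-0.084), ribosomal proteins (0.14), resting fibroblast (-0.29) and TCA cycle (0.077) ended with library weights. Leaving out the short-gene libraries, the calls of fatty acid oxidation (0.079), Hippo (-0.018), endothelial (-0.16), smooth muscle (-0.030), ribosomal proteins (0.026) and TCA cycle (0.055) ended. Without the 3 libraries highest in atrial genes those of cell cycle (-0.13), ion channels (0.11) and endothelial (-0.14) did. Across their alternatives the adjusted p ran from 1.55e-15 to 0.752. Acad11, an acyl-CoA dehydrogenase (6.82 ± 0.566 against 4.46 ± 0.525 FPKM; 0.52, SE 0.084, adjusted p = 0.233), Smpdl3a (0.71, SE 0.13, adjusted p = 0.303) and Ehhadh (0.56, SE 0.10, adjusted p = 0.303) were nearest to passing among genes higher in the inhibitor group. Med27 (-0.36, SE 0.080), Colgalt2 (-0.45, SE 0.10) and Tcaf1 (-0.43, SE 0.10) were nearest among those lower, each with an adjusted p = 0.619. No single gene passed an adjusted p of 0.05 by limma, with a smallest adjusted p of 0.233 over 12935 genes, and voom on the recovered reads also called 0. At an unadjusted p under 0.05, 978 genes differed, 496 higher and 482 lower, where 647 would by chance. That count was 511 without inhibitor 2. The libraries of both groups did not overlap for 3.55% of genes, against 2.86% by chance. Of 36 lists, 12 passed camera at its preset correlation, 4 upward and 8 downward, and 0 with an estimated correlation or by fry.

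The camera test called 21 of the 36 lists in at least 1 comparison. The other 15 were MHC class II, Schwann cells, T and NK cells, Wnt signalling, adipocytes, apoptosis and p53 targets, cardiac stress genes, circadian clock, cytokines and chemokines, gap junctions, glycolysis and hypoxia, heat shock proteins, mitochondrially encoded genes, sarcomere and calcium handling, and the unfolded protein response. For none of these 15 did a member pass when adjusted over the list alone or over all genes.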

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

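The tests of the length trend, of fatty acid oxidation minus sarcomere genes and of the atrial genes were chosen only after the results were seen, while those of Hippo against sarcomere genes and of genes at 2 levels were set beforehand. Of 480 groups of 4 libraries tested, 35 held 1 library whose gap to the nearest other, as a ratio to the group's range, exceeded Dixon's 95% critical value. By chance about 1 in 20 groups, or 24 here, would do so. Values below are FPKM for genes and mean log2 for lists, the library apart against the range of the other 3 of its group, with the ratio of gap to range. Control 2 stood apart for Flt1 (26.4 against 34.9 to 36.02, ratio 0.882), Ccnb1 (2.63 against 1.46 to 1.66, ratio 0.8291), Fap (8.24 against 5.38 to 5.69, ratio 0.892), the Hippo list (3.296 against 3.38 to 3.39, ratio 0.927) and the gap junction list (4.95 against 5.12 to 5.15, ratio 0.840). In control 3 this held for Suclg2 (63.4 against 70.1 to 70.7, ratio 0.924) and Hba-a2 (1828 against 955 to 1085, ratio 0.850). For control 4 the values apart were those of Etfdh (149 against 170.0 to 172, ratio 0.896) and the fatty acid oxidation list (6.84 against 7.26 to 7.34, ratio 0.8292). Cx43-wt 1 stood apart for Cdh5 (99.5 against 71.1 to 75.2, ratio 0.855) and Cxcl10 (7.91 against 1.77 to 2.70, ratio 0.847). In Cx43-wt 3 this held for Rpl7a (89.2 against 18.1 to 22.2, ratio 0.942). For Cx43-wt 4 the values apart were those of Csnk1e (13.3 against 16.02 to 16.2, ratio 0.923) and Ctnnb1 (100.49 against 123 to 124, ratio 0.951). Cx43-wt 5 stood apart for Sla (2.45 against 1.74 to 1.85, ratio 0.846), Kazald1 (8.12 against 4.25 to 4.77, ratio 0.867), Comp (7.54 against 0.210 to 1.22, ratio 0.862), Cd68 (8.86 against 5.51 to 5.96, ratio 0.866) and the cell cycle list (1.96 against 1.504 to 1.51, ratio 0.977). In S282A 4 this held for Yap1 (50.7 against 42.2 to 43.5, ratio 0.848), Col6a2 (103 against 132 to 134, ratio 0.922) and the TCA cycle list (7.72 against 7.43 to 7.46, ratio 0.926). For S282A 6 the values apart were those of Asna1 (55.3 against 40.00 to 41.6, ratio 0.896). S282A 7 stood apart for Adra1d (2.89 against 2.23 to 2.33, ratio 0.838), Klf6 (24.8 against 16.3 to 16.7, ratio 0.948) and Loxl1 (36.6 against 31.8 to 32.4, ratio 0.873). In inhibitor 1 this held for the endothelial list (6.25 against 5.98 to 6.02, ratio 0.836). For inhibitor 2 the values apart were those of Smpdl3a (26.7 against 21.2 to 22.02, ratio 0.849) and Col6a2 (74.7 against 91.7 to 94.9, ratio 0.843). Inhibitor 4 stood apart for Mllt6 (15.7 against 19.1 to 19.6, ratio 0.879), Fat4 (1.78 against 2.98 to 3.11, ratio 0.906), Tjp1 (25.8 against 38.4 to 38.9, ratio 0.962) and the oxidative phosphorylation list (8.997 against 8.55 to 8.56, ratio 0.966). In inhibitor 5 this held for Cd68 (6.99 against 4.92 to 5.26, ratio 0.835) and Acta2 (184 against 53.2 to 66.2, ratio 0.901).

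In S282A against Cx43-wt, the Hippo list was higher by 0.089 and fatty acid oxidation genes differed by -0.38; a length trend between libraries and a lower share of cardiomyocytes were tested beside an effect of the exchanged serine. With each library's length trend removed, fatty acid oxidation stood at -0.34 (camera adjusted p = 5.93e-08, and 0.410 with an estimated correlation, at which it did not pass before either, 0.489). Without the short-gene libraries it stood at -0.28 (camera adjusted p = 0.000793, and 0.982 with an estimated correlation). That fit kept Cx43-wt 1 (7.26) and Cx43-wt 5 (7.05), the latter below S282A 1 (7.09). Removing the trend thus kept 91.3% of the mean difference. Camera at its preset correlation called a median of 10.5 lists in the other splits of these 8 libraries, so its p does not decide against that trend. For the Hippo list the difference was 0.058 with the trend removed (camera adjusted p = 0.0321; 0.244 with an estimated correlation; two-sided exact p = 0.0286, the smallest possible), as the SDs of the library means went from 0.026 and 0.064 to 0.0073 and 0.027, and 0.035 without the short-gene libraries (camera adjusted p = 0.341, with a range of 0.000404 to 0.514 over its alternatives), so a part played by gene length cannot be told apart from a difference between the groups. For the share of cardiomyocytes, fatty acid oxidation minus sarcomere genes differed by -0.25 (two-sided exact p = 0.0571) and smooth muscle minus macrophage genes by 0.35 (two-sided exact p = 0.0857), and the Hippo and sarcomere means had r = -0.52 with group means removed (two-sided permutation p = 0.0369; rho = -0.48, p = 0.0639) and r = -0.55 over all libraries (Benjamini-Hochberg value 0.0417 over 6 relations; rho = -0.36, value 0.170). The first r passed the value set beforehand, but r over all libraries was -0.35 (two-sided permutation p = 0.212) without inhibitor 4 and Cx43-wt 4, the 2 farthest libraries, so a lower share of cardiomyocytes cannot be told apart either, and the exchanged serine stays an open, untested explanation.

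Nppa, whose peptide the atria secrete, ran from 5.71 to 4411 FPKM (773-fold), Myl7, the atrial myosin light chain, from 0.331 to 401 (1210-fold) and Nppb from 30.9 to 462 (15-fold), with wide ranges inside single groups. Nppa followed Myl7 with group means removed (Spearman rho = 0.921, Pearson r = 0.960, each with a two-sided permutation p = 1e-05, the smallest 100000 permutations can give; Benjamini-Hochberg value 6e-05 over 6 relations; r = 0.913 over all libraries without control 1 and control 3, the 2 farthest). A share of atrial tissue in the sampled piece may therefore account for these levels, as a hypothesis tested on the libraries in which it was noticed. Nppa followed Nppb less closely (rho = 0.627, two-sided permutation p = 0.0115, Benjamini-Hochberg value 0.0222, r = 0.680, and r = 0.624 over all libraries without the same 2). The range of Nppb was narrow beside that of Nppa. Nppb still followed Nppa and the rule was set after the values were seen, so a stress response of ventricular cells stays open. The atrial markers Sln and Myl4 were high in the same 10 libraries as Myl7. Not every atrial marker followed: Bmp10 stood at 0 to 0.0886 FPKM in inhibitor 5, S282A 4 and control 2, where Myl7 stood at 70.8 to 121. The labels give the tissue as myocardium without naming a chamber, 1 of the 9 atrial markers also stands in the cardiac stress list, and no biological explanation by group was tested.

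At a mean of at least 5 FPKM, 21 of 8139 genes had their libraries at 2 levels at least 2 log2 units apart, with at least 3 libraries on each side, and 0 of the 21 separated any groups. Fam111a, singled out after its values were seen, stood at 43.6 to 92.7 FPKM in 10 libraries and 0.591 to 1.29 in 6; 3 of the 21 were atrial markers (Sln, Myl7 and Myl4), and 4 were high in the 4 short-gene libraries and in no other. A strain or donor variant may set such levels, in which case neighbouring genes should share their split: the 1 pair within 1 Mb had an absolute correlation of 0.127 against a mean of 0.262 between chromosomes (one-sided permutation p = 0.732), which met the bound set beforehand but is 1 pair and decides nothing. Reads shared with near-identical copies could do so too, and 41.7% of the 12 named genes (5) had a named copy or pseudogene against 18.1% of 7585 other genes (two-sided Fisher exact p = 0.0504). Neither explanation could be excluded, and no biological explanation was tested.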

How the results depend on the processing

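The tests by voom, by scaling to total recovered reads, with the length trend removed, without the 4 short-gene libraries at either correlation, without the 3 libraries highest in atrial genes, with length slope and atrial mean as covariates, by fry and by exact permutation of list means were chosen only after seeing the data. Single genes stayed at 0 past the threshold in all 5 comparisons under the other settings tried, except without the 4 short-gene libraries and in the fits without 1 library named below; limma's unadjusted counts stand beside each comparison. Lists past the threshold numbered 0 in each of the 5 comparisons with an estimated correlation, by fry and by exact permutation, where camera at its preset correlation gave 15, 10, 11, 9 and 12. An estimated correlation allows for members of a list varying together between libraries beyond the preset 0.01. An exact permutation, with 0.0286 its smallest p, could pass a list only if most of the 36 reached that p. Its 0 therefore decides nothing. The deposited FPKM already carried the median-of-ratios scaling, so using them unscaled moved nothing and tests nothing.

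Without the 4 short-gene libraries, 3 genes passed in S282A against Cx43-wt (LOC100910678 1.92, RT1-CE7 0.83 and AABR07073045.1 -2.32), 4 in Cx43-wt against control (these 3 at -1.90, -0.69 and 2.54, and Retsat 1.63), 1 in the inhibitor group against control (Retsat 1.88) and 0 in the other 2; these genes were singled out after their values were seen. The lists then numbered 6 in S282A against Cx43-wt and 6 in the inhibitor group against S282A, and 0 in each of the 5 comparisons with an estimated correlation. Cx43-wt then had 2 libraries, control and the inhibitor group 3 each. In S282A against Cx43-wt matrix genes stood at -0.077, where the mean changed sign, and ribosomal proteins at -0.027, where it kept its sign and camera's direction turned. In Cx43-wt against control cell cycle stood at 0.026, matrix at 0.39 (adjusted p = 6.85e-07, and 0.740 with an estimated correlation), carried by Cx43-wt 5 alone, matrix proteases at 0.078, myofibroblast at 0.25 and TGF-beta at 0.067. Without the 3 libraries highest in atrial genes the atrial mean was 1.22 in S282A against Cx43-wt and -0.45 in Cx43-wt against control. With library weights the lists numbered 17 in Cx43-wt against control and 6 in the inhibitor group against S282A. With the replicate number as a replicate block they numbered 4 in S282A against control and 18 in Cx43-wt against control, and in the former erythroid genes stood at -0.21, with the mean of the other sign, and ribosomal proteins at -0.11, where only camera's direction turned. The block set S282A 6 and S282A 7 aside, so its S282A values rested on S282A 1 and S282A 4. The other calls that the block ended are given beside each comparison. Quantile normalization ended the calls given beside each comparison. Of 15 same-number pairs of libraries 6 correlated above 0.1 and 4 below -0.1 (-0.22 to 0.26), and 5 libraries were closest to 1 of their own number, so the numbers were not taken to pair samples. The cause was not tested for these changes.

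The Hippo mean in S282A against Cx43-wt was 0.089 with an estimated correlation (adjusted p = 0.489), by fry (0.398) and by exact permutation (0.514), 0.035 without the 4 short-gene libraries (0.341) and 0.041 with covariates (0.0546); 27 of its 32 alternatives kept the call, the deposited FPKM not counted, with adjusted p from 0.000404 to 0.514, and leaving out 1 library gave 0.069 to 0.11. In the fits without 1 library, genes past the threshold ranged from 0 to 0 in S282A against Cx43-wt and against control, 0 to 1 in Cx43-wt against control (Retsat 1.62, adjusted p = 0.0318, without control 2), 0 to 1 in the inhibitor group against control (Retsat 1.90, adjusted p = 0.00499, without control 2) and 0 to 1 in the inhibitor group against S282A (Ehhadh 0.66, adjusted p = 0.0447, without inhibitor 5). Lists ranged from 12 to 16 in S282A against Cx43-wt, 8 to 12 in S282A against control, 8 (without control 2) to 19 (without Cx43-wt 1 or Cx43-wt 5) in Cx43-wt against control, 3 (without inhibitor 2) to 10 (without control 3) in the inhibitor group against control and 5 (without inhibitor 4) to 13 (without S282A 4) in the inhibitor group against S282A, where 6 passed without S282A 7. Matrix genes in Cx43-wt against control ranged from -0.47 without Cx43-wt 5 to 0.061 without Cx43-wt 3. Hippo components passed in Cx43-wt against control with library weights (-0.073, adjusted p = 0.0187), with the replicate block (-0.061, adjusted p = 0.0327) and without Cx43-wt 1 (-0.061, adjusted p = 0.0372). Again without the deposited FPKM, over 59 list results and 1882 alternative values, 1505 kept direction and side of the threshold, 362 fell short of it, 3 newly passed and 12 turned. Over 340 named-gene results and 9788 values, 9787 kept their side of the threshold and 1 newly passed, with 91 of the other sign. With a mean of at least 5 FPKM 31 lists kept enough members, and the other lists and named genes under that level have no value there. At this depth 3 reads in a gene of 1 kb were worth at most 0.218 FPKM, under the filter of 1 FPKM.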

Other observations

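The tests of the 12 other libraries against the 4 controls and the relations of Kcnj3 with Myl7 and of matrix with adipocyte genes were chosen only after the results were seen; the counts over other splits were planned. Interferon-induced genes, which respond to virus and damage signals, were higher in the 12 libraries of the other groups than in the 4 controls for 22 of 23 members, by 0.28 (two-sided exact p = 0.0352 over 1820 splits, adjusted p = 0.815 over 36 lists). In 9 of the 12 libraries their mean lay above all controls, which ranged from 3.09 to 3.23, and in 1, Cx43-wt 5 (3.08), below them. Macrophage genes stood at 0.27 (12 of 14 higher, exact p = 0.0989), immediate early genes at -0.41 (1 of 17 higher, exact p = 0.0857) and cell cycle genes at -0.25 (3 of 21 higher, exact p = 0.113), each two-sided with an adjusted p = 0.815. By camera 8 lists passed in this contrast, and 0 with an estimated correlation (smallest adjusted p = 0.682) or by exact permutation. No single gene passed by limma (smallest adjusted p = 1.000, 338 genes at an unadjusted p under 0.05).

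Kcnj3, the atrial channel gene nearest to passing against control, ran from 8.18 to 20.6 FPKM and did not follow Myl7 beyond chance (r = 0.378, two-sided permutation p = 0.149, Benjamini-Hochberg value 0.149; rho = 0.447, p = 0.0853, value 0.102; r = 0.258 without S282A 6 and control 1). The matrix and adipocyte means had r = 0.460 (two-sided permutation p = 0.0730, Benjamini-Hochberg value 0.0876; rho = 0.462, p = 0.0744, value 0.102; r = 0.257 without Cx43-wt 3 and Cx43-wt 5) and r = 0.639 with group means removed (p = 0.00526), among the 6 relations computed. Between libraries the log2 values had a Pearson r of 0.949 to 0.975 within groups and 0.940 to 0.980 between them.

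Each comparison was repeated over the 35 ways of parting its 8 libraries into 4 and 4. At an unadjusted p under 0.05, S282A against Cx43-wt had 1105 genes and 7 of the 35 splits had as many (highest other 1785), S282A against control 539 and 9 splits (853), Cx43-wt against control 360 and 24 splits (2154), the inhibitor group against control 671 and 15 splits (1989) and the inhibitor group against S282A 978 and 8 splits (1598). For lists past camera's threshold, S282A against Cx43-wt had 15 and 8 splits had as many (highest other 18), S282A against control 10 and 9 splits (17), Cx43-wt against control 11 and 21 splits (19), the inhibitor group against control 9 and 16 splits (15) and the inhibitor group against S282A 12 and 10 splits (16). Chance could not be excluded for any of these 10 counts. Some splits had several times the labelled count of genes, as in Cx43-wt against control and in the inhibitor group against control. What set these splits apart was not tested.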
